A study of Mus musculus with 6 samples.

How the data were processed

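RNA from the cerebellum of 6 mouse pups of the C57BL/6 strain, aged 6 days, had been sequenced as single-end short reads, with 1 library per animal. The labels placed 3 animals in the wild type group and 3 in the SnoN conditional knockout group (SnoN cKO). Each genotype had 1 animal labelled female and 2 labelled male. Replicate numbers came from the sample titles. The library kit named in the labels does not record the strand of a read, so reads of a gene and of an overlapping or antisense partner could not be told apart. This applied to the Hox genes, which lie in clusters with antisense transcripts. Near-identical copies such as the alpha and beta globin genes could also share reads, and their counts are uncertain.

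The authors deposited raw read counts per gene, with the Ensembl identifier and symbol of each gene, for all 6 libraries in a single table. Per the submitters' processing notes, STAR 2.0.4b, Subread (version not given) and featureCounts 1.4.5 were used with the mm9 genome build. The notes did not tie each tool to a step, and the gene annotation was not given in the sources used here. No coordinates are reported, because the annotation at hand was of another build.

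The table held 41228 genes. In 140 cases, covering 112 symbols, a symbol was listed again under a further Ensembl identifier with the same counts in all 6 libraries. These repeats held 0.465% of the counts and were kept once, a choice made after the values had been examined. Where a symbol was listed with different counts, the entry with most reads kept the plain symbol. In 24 entries the symbol had been turned into a date, as spreadsheet programs do, and none of these was named. After removal of repeats, 26195 genes had at least 1 count. Entries without an Ensembl identifier numbered 594, each with a symbol, and were kept. They held between 0.0168% and 0.0177% of the counts of a library.

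The total count per library was 12605870, 15050176 and 12815564 in wild type 1, 2 and 3, and 12639806, 14683166 and 17757711 in SnoN cKO 1, 2 and 3. Every pair of libraries differed by more than sampling noise. The lowest chi-square per degree of freedom over the 15 pairs was 2.67, so no library was counted as a repeat of another.

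The genotype comparison used edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with edgeR's filterByExpr by genotype at its minimum count of 10, which left 15457 genes. Libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood test of genotype, two-sided, was fitted to all 6 libraries without covariates, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The common biological coefficient of variation was 9.71%. Levels are given as CPM, the deposited counts divided by the TMM-scaled library totals of the genes that passed the filter. The log2 CPM of the list scores came from edgeR's cpm function. The standard error of a log2 fold change was derived from the fold change and the F statistic. An exact permutation of 3 against 3 libraries cannot give a two-sided p under 0.1, so none was used for single genes. Skil, the targeted gene, was judged on its unadjusted p as a single gene chosen in advance.

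The gene lists, 20 in all, covered DNA replication, mitosis, granule precursor and Sonic hedgehog response, postmitotic migrating granule neuron, maturing granule neuron, TGF-beta and BMP target, SnoN relative or partner, p53 target and apoptosis, 11 cell types or tissues that a cerebellar dissection can hold, and immediate early and stress genes. They were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, and with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera compares the members of a list with all other genes, whereas fry asks whether the members move on balance in a single direction. The score of a list in a library was the mean log2 CPM of its members, minus the mean over the 6 libraries.

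Named genes were chosen by rule. The rule took 12 genes fixed in advance (Skil, Ski, Mycn, Pax6, Atoh1, Gli1, Ccnd1, Ccnd2, Mki67, Pcna, Neurod1 and Gabra6), the 10 largest changes per direction among genes past the threshold whose genotypes did not overlap, up to 4 members per list with the smallest p, and Xist with 4 Y-linked genes for a check of sex. Where fewer than 5 genes passed in a direction, the 5 with the smallest p in that direction were named as not past the threshold, at a mean of at least 1 CPM and leaving out clone-style symbols. The text gives examples of the list members selected by the rule, and a positive member of the migrating granule neuron list is not reported here. Other genes were chosen after their values were seen and are given as such. The groups, lists, main tests and first set of alternatives were fixed before the data were examined.

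Two-factor fits with the labelled sex, with and without its interaction with genotype, used the same edgeR test. Sex was taken from the labels in these fits, also where the sex-linked transcripts of a library went against its label. With 1 animal labelled female per genotype, those animals were assumed to vary like the others.

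The alternatives set in advance were DESeq2 1.42.0, DESeq2 size factors in edgeR, scaling by library total alone, no filter on low counts, a filter of 1 CPM in 3 libraries, limma-voom, edgeR's likelihood ratio test, the labelled sex as a covariate, the replicate number as a block, an adjusted p of 0.1, each library left out in turn, the 4 libraries labelled male alone, and removal of blood, choroid plexus, meninges, brainstem and mitochondrial genes. Alternatives added after seeing the data were removal of ribosomal-type RNA genes, removal of 2 pairs of libraries, and the brainstem score as a covariate.

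The code was tested on simulated counts with the means, sizes and dispersions of these libraries and 15457 genes. Of 50 genes changed at each size in the comparison of SnoN cKO with wild type, edgeR's quasi-likelihood test recovered 2% at 1.2-fold, 46% at 1.5-fold, 86% at 2-fold and 98% at 3-fold, and it called 8 unchanged genes. On the same counts limma-voom and DESeq2 called 10 unchanged genes each, and edgeR's likelihood ratio test called 21. A shift of 0.15 on the log2 scale in the DNA replication list was recovered by camera with the preset correlation, with 0 other lists called. In 20 simulations without any change, 32 of 400 list tests had an unadjusted p under 0.05 and 4 passed after adjustment, 2 for the Purkinje list, 1 for the choroid plexus list and 1 for the red blood cell list. Simulated genes varied independently of each other, so these figures do not cover genes that vary together. That step was added after a first simulation had called lists without a shift.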

Results

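Cerebella of 6 mice at postnatal day 6 were compared by RNA sequencing, 3 from wild type animals and 3 from animals with a conditional knockout of SnoN. SnoN, the product of Skil, is a transcriptional regulator of the Ski family that binds Smad proteins and restrains signalling by transforming growth factor beta (TGF-beta). At this age the outer layer of the cerebellar cortex holds dividing granule neuron precursors, which Sonic hedgehog drives to proliferate, and the series concerns the part SnoN plays in that proliferation. Libraries held between 12605870 and 17757711 counts on genes. Values are means ± SD of 3 libraries per genotype unless stated otherwise, in CPM, the counts of a gene scaled by the TMM-scaled library total.

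Skil was lower in each SnoN cKO library than in each wild type library. Its level was 88.6 ± 1.0 CPM in wild type (SD, n = 3) and 76.1 ± 1.39 CPM in SnoN cKO (SD, n = 3), a log2 fold change of -0.22 (SE 0.04) and a difference of -14.2%. As a single gene chosen in advance, Skil (ENSMUSG00000027706) passed edgeR's quasi-likelihood test with an unadjusted p of 0.000379, and it ranked 7 of 15457 genes by p. Its adjusted p over all genes was 0.637. The paralogue Ski was at 226 ± 12.2 CPM in wild type and 228 ± 9.23 CPM in SnoN cKO. The deleted exons and the cells in which deletion took place are not given in the sources used here, and Skil reads were not split by exon or cell.

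The genes fixed in advance for granule neuron precursors differed little between genotypes. Atoh1, the transcription factor that specifies these precursors, was at 27.2 ± 1.29 CPM in wild type and 30.7 ± 3.07 CPM in SnoN cKO, with a log2 fold change of 0.18 (SE 0.08). Pax6, a transcription factor of granule cells, had a log2 fold change of 0.11 (SE 0.06). The Sonic hedgehog targets Gli1, Mycn, Ccnd1 and Ccnd2 had log2 fold changes of 0.01, 0.05, 0.13 and 0.09, with SE of 0.08, 0.07, 0.09 and 0.05. Mki67, a marker of dividing cells, was at 657 ± 35.2 CPM in wild type and 705 ± 41.9 CPM in SnoN cKO. Pcna, the sliding clamp of replication, was at 87.2 ± 1.78 CPM in wild type and 97.6 ± 9.66 CPM in SnoN cKO, higher in each SnoN cKO library than in each wild type library. Neurod1, a factor of differentiating granule neurons, and Gabra6, a receptor subunit of mature granule neurons, had log2 fold changes of 0.02 (SE 0.08) and 0.00 (SE 0.29). None of these genes passed edgeR's test, with adjusted p between 0.637 and 0.999.

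Among the remaining genes, those with the smallest p differed by modest amounts. Eln, which encodes elastin, was higher in SnoN cKO at 161 ± 7.26 CPM against 124 ± 10.2 CPM, a log2 fold change of 0.38 (SE 0.06). Scrg1, Ssbp4, Fam129c and Magoh, a subunit of the exon junction complex, followed with log2 fold changes of 0.52, 0.30, 0.91 and 0.25. Ncan, a chondroitin sulfate proteoglycan of the brain's extracellular matrix, was lower at 375 ± 23.7 CPM against 474 ± 27.1 CPM, a log2 fold change of -0.34 (SE 0.06). Tenm3, a teneurin involved in synaptic partner choice, Tmem150c and the large cadherin Fat4 had log2 fold changes of -0.35, -0.25 and -0.22. In each of these 9 genes the libraries of the genotypes did not overlap. Of all 15457 genes, 13.7% were separated in this way, where chance gives 10%.

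None of these genes passed the adjusted threshold. By edgeR's quasi-likelihood test 0 of 15457 genes had an adjusted p under 0.05, and the smallest was 0.637. At an unadjusted p under 0.05 there were 1187 genes, 496 higher and 691 lower in SnoN cKO, where chance gives 773 on average. Other splits of the 6 libraries into 3 against 3 gave between 299 and 1742 such genes. With the real split included, 2 of 10 splits gave as many. The excess over 773 alone therefore does not set the genotypes apart. limma-voom also called 0 genes. DESeq2 was run without the filter on low counts, over 26169 genes. It called 6 genes, with Eln higher and Ncan, Tenm3, Ank2, Cbln2 and Col11a2 lower. edgeR's likelihood ratio test called 5 genes, with Fam129c and 6430573F11Rik higher and Hoxa5, Cbln2 and Hs3st2 lower. On simulated counts of 15457 genes the likelihood ratio test called 21 unchanged genes and DESeq2 10, against 8 for the quasi-likelihood test. By the quasi-likelihood test without the filter on low counts 39 genes passed, 8 higher and 31 lower, with log2 fold changes between -7.68 and 6.07. Among them were Nrgn, Lhx9 and Lhx2, each far higher in wild type 1 than in any other library. The SE of Lhx9 was 0.33 in that fit and 0.59 with the filter. Those 39 calls therefore reflected the spread between libraries poorly and carry little weight. Ank2, Cbln2, Col11a2, 6430573F11Rik and Hs3st2 were named after their values were seen.

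**Figure D1:**
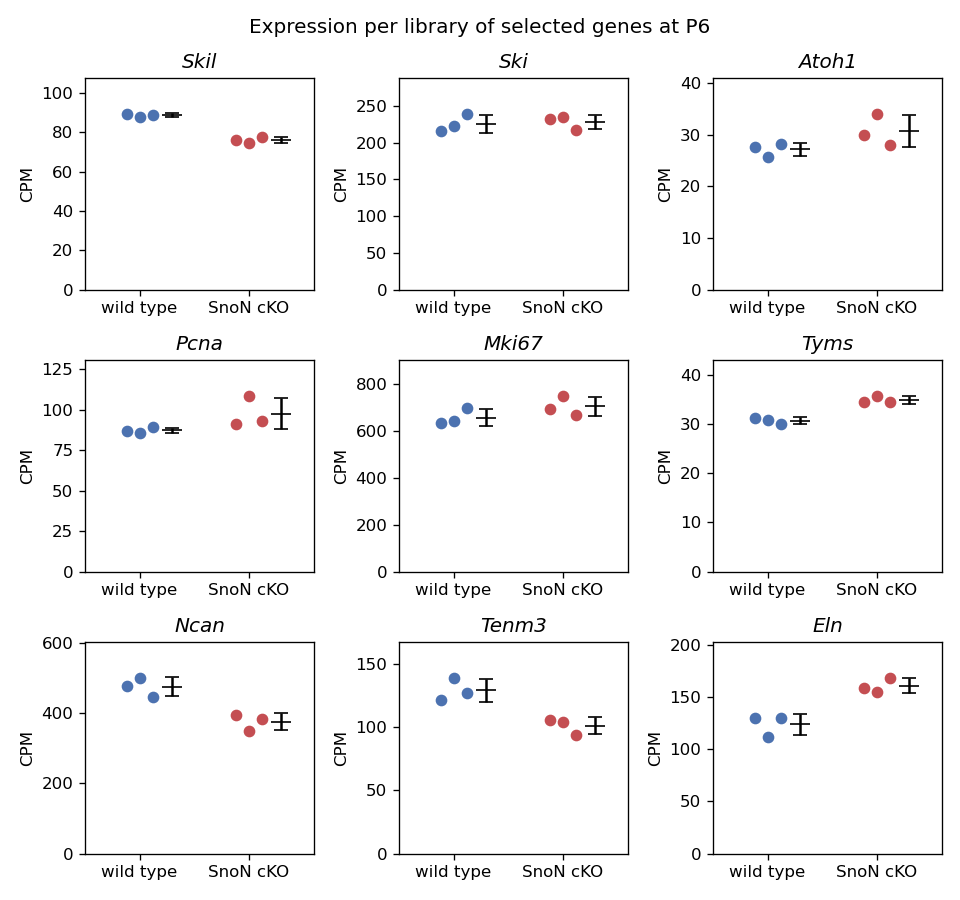
CPM of 9 genes (vertical axes, starting at 0) in wild type and SnoN cKO, with a point per library and the mean ± SD of 3 libraries as a black bar. Skil sits at 88.6 CPM in wild type and 76.1 CPM in SnoN cKO with no overlap, while Mki67 and Ski overlap between genotypes.

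Genes of DNA replication were slightly higher in SnoN cKO as a list. Of 42 measured members 41 had a positive log2 fold change, with a median of 0.14. The thymidylate synthase gene Tyms was at 34.9 ± 0.749 CPM against 30.7 ± 0.689 CPM, and the replicative helicase gene Mcm2 at 148 ± 13.8 CPM against 129 ± 5.27 CPM. Chaf1b, a subunit of the chromatin assembly factor, and Ccne2, a cyclin of the entry into S phase, had log2 fold changes of 0.23 (SE 0.07) and 0.34 (SE 0.12). No member passed on its own, with 0 genes adjusted over the list alone and 0 over all genes tested. The list rose by camera with the preset correlation (adjusted p = 2.29e-12), and the call was lost with an estimated correlation (adjusted p = 0.671 with an estimated correlation).

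The mitosis list rose as well, by a median log2 fold change of 0.09, with 36 of 40 members positive and an adjusted p of 1.54e-07 by camera. With an estimated correlation its adjusted p was 0.671. Cdc20, an activator of the anaphase-promoting complex, was at 84.1 ± 4.46 CPM against 76.2 ± 3.20 CPM. Aurka, a mitotic kinase, was at 40.6 ± 3.05 CPM against 36.3 ± 0.711 CPM, while Cdca3 and Sgol1, which protects sister chromatid cohesion, had log2 fold changes of 0.14 and 0.15. The list of granule precursor and Sonic hedgehog response genes rose by a median log2 fold change of 0.09, with 19 of 22 members positive (adjusted p = 0.00089 by camera, adjusted p = 0.671 with an estimated correlation). In it, the Wnt antagonist Sfrp1 was at 249 ± 29.1 CPM against 212 ± 16.5 CPM, the Polycomb gene Bmi1 had a log2 fold change of 0.14 (SE 0.06) and the homeobox gene Barhl1 of 0.18 (SE 0.08). No member of either list passed, adjusted over the list alone or over all genes tested.

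SnoN cKO 2 had the highest score of each of these 3 lists. Its DNA replication score was 0.18, against 0.01 and -0.003 in SnoN cKO 1 and 3 and between -0.08 and -0.04 in wild type. Without SnoN cKO 2 the median of the DNA replication list was 0.08 (adjusted p = 0.000119 by camera) and that of the mitosis list 0.05 (adjusted p = 0.0128). The granule precursor list no longer passed without SnoN cKO 2 (median 0.02, adjusted p = 0.509) or without wild type 1 (median 0.04, adjusted p = 0.12). With SnoN cKO 1 and 2 both left out, an alternative chosen after seeing the data, the DNA replication list kept its call with a median of 0.04 (adjusted p = 0.0307) and the mitosis list did not pass (adjusted p = 0.404). SnoN cKO 2 also had the lowest score of brainstem genes, and with that score as a covariate, likewise chosen after seeing the data, the median of the DNA replication list was 0.01 (adjusted p = 0.673).

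Genes of later stages of the granule neuron lineage did not pass as lists. Of 18 measured genes of postmitotic migrating granule neurons 12 had positive log2 fold changes, with a median of 0.02 and an adjusted p of 0.568 by camera. Cdkn1b, an inhibitor of the cell cycle, had a log2 fold change of 0.09 (SE 0.05), the neuronal tubulin gene Tubb3 of -0.10 (SE 0.05) and the adhesion protein gene Astn1 of -0.09 (SE 0.04). Genes of maturing granule neurons split evenly, 9 positive and 9 negative, with a median of 0.01, a mean of -0.03 and an adjusted p of 0.792 for a lower list. Cbln3 was at 21.3 ± 1.51 CPM against 17.2 ± 1.6 CPM, and the calcium sensor gene Vsnl1 at 60.7 ± 9.37 CPM against 75.5 ± 6.14 CPM. No member of these lists passed, adjusted over the list alone or over all genes.

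Targets of TGF-beta and BMP signalling did not pass as a list. Of 20 members 10 had positive and 10 negative log2 fold changes, with a median of 0.00, a mean of -0.05, and an adjusted p of 0.792 for a lower list by camera. Id2, an inhibitor of basic helix-loop-helix factors, was at 182 ± 8.11 CPM against 164 ± 1.71 CPM, Cyr61 had a log2 fold change of -0.38 (SE 0.17) and the Notch ligand Jag1 of -0.21 (SE 0.11). The relatives and partners of SnoN had 11 of 15 members positive and an adjusted p of 0.227, with log2 fold changes of 0.11, 0.07 and 0.09 for Smad4, Smad2 and Smad3, and the list rose without wild type 3 or SnoN cKO 3 (adjusted p of 0.0205 and 0.0132). With an estimated correlation and all libraries its adjusted p was 0.747. Targets of p53 and apoptosis genes had 11 of 17 members negative and an adjusted p of 0.568, with Zmat3, which lies near Skil on its chromosome, at -0.18 (SE 0.08) and Bax at 0.07 (SE 0.04). Immediate early and stress genes had 7 positive and 7 negative members and an adjusted p of 0.985. Npas4, an activity-regulated factor, had a log2 fold change of -0.62 (SE 0.21). In these 4 lists 0 genes passed, adjusted over the list alone or over all genes tested.

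**Figure D2:**
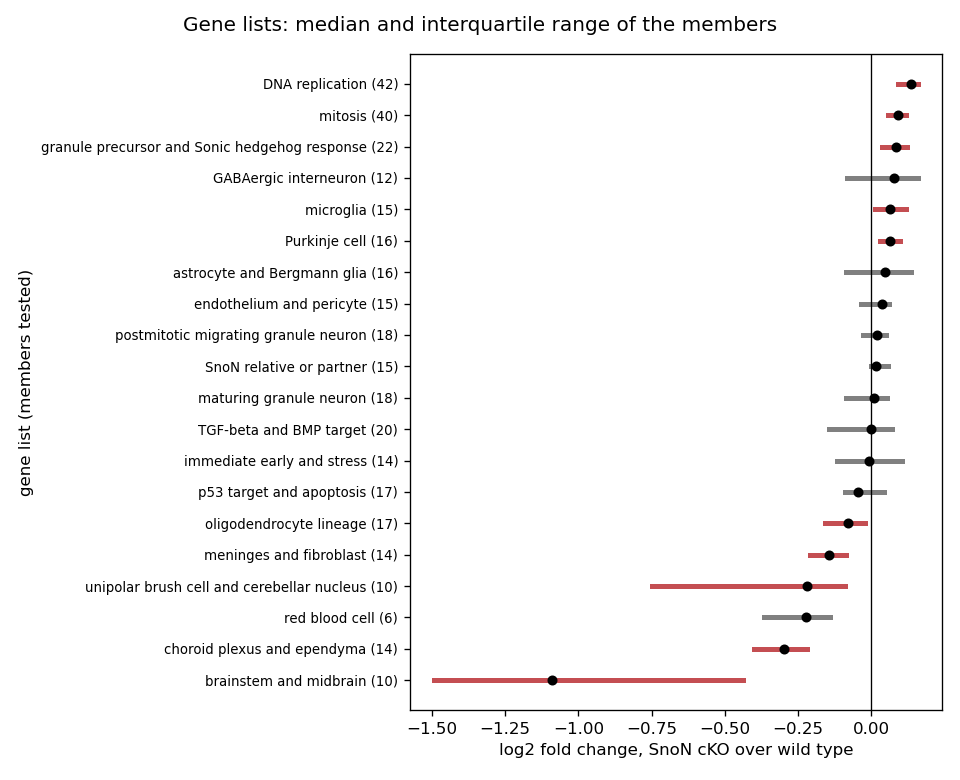
Median (black point) and interquartile range (bar) of the log2 fold changes of the members of each of 20 gene lists, SnoN cKO over wild type. Red bars mark the 10 lists past an adjusted p of 0.05 by camera with the preset correlation, among them DNA replication at a median of 0.14 and brainstem and midbrain at -1.09.

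Genes of tissue next to the cerebellum were lower in SnoN cKO. All 10 measured members of the brainstem and midbrain list had negative log2 fold changes, with a median of -1.09. The rest of the 26 listed genes did not pass the filter on low counts. A gene near the floor can pass through its wild type libraries alone. Hoxa5 did so, with counts of 17, 28 and 13 against 3, 0 and 6 in SnoN cKO. Such a member can only be negative, so the count and the median may in part reflect the filter. Hoxa5, a homeobox gene of the caudal hindbrain and spinal cord, was at 0.196 ± 0.179 CPM against 1.4 ± 0.428 CPM, Hoxa3 at 0.518 ± 0.436 CPM against 1.65 ± 0.872 CPM, and Tal1, a factor of midbrain and hindbrain interneurons, at 3.82 ± 0.449 CPM against 5.01 ± 0.318 CPM. The list fell by camera with the preset correlation (adjusted p = 2.84e-09), and with an estimated correlation its adjusted p was 0.671. Hoxa5 passed when adjusted over the list alone (adjusted p = 0.00706 from edgeR), and 0 genes passed over all genes tested. Without wild type 2 Hoxa5 did not pass (lowest adjusted p over the list alone 0.052), and without wild type 3 or SnoN cKO 3 there were 4 and 9 members past it. The score of the list was lowest in SnoN cKO 2 at -1.51, and was -0.49 and 0.33 in SnoN cKO 1 and 3 against 0.55, 0.98 and 0.14 in wild type 1, 2 and 3. Without wild type 2, SnoN cKO 2 or SnoN cKO 3 the median moved to -0.57, -0.72 and -2.12, each still past the threshold.

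Unipolar brush cell and cerebellar nucleus genes fell in the same direction, with 10 of 10 members negative and a median of -0.22 (adjusted p = 3.77e-05 by camera, adjusted p = 0.671 with an estimated correlation). Meis2, Lhx9, Slc17a6 and Lhx2 passed when adjusted over the list alone (adjusted p = 0.0287 from edgeR for each), and 0 genes passed over all genes. Without wild type 1 none of them passed (lowest adjusted p over the list alone 0.112), and without wild type 2, SnoN cKO 2 or SnoN cKO 3 there were 2 each time. Slc17a6, the vesicular glutamate transporter of nuclear neurons, was at 93.6 ± 17.9 CPM against 120 ± 3.67 CPM. Without wild type 2 or SnoN cKO 2 the median of the list was -0.12 and -0.08, still past the threshold. The homeobox genes Lhx9 and Lhx2 were at 22.4 and 7.9 CPM in wild type 1 and at most 5.3 and 2.96 CPM in the other libraries. Without wild type 1 the log2 fold changes of Lhx9 and Lhx2 were -0.85 and -0.73, against -1.96 and -1.47 with all libraries. Oligodendrocyte lineage genes fell by a median of -0.08, with 13 of 17 negative (adjusted p = 0.0325, adjusted p = 0.671 with an estimated correlation). The myelin gene Mog was at 5.66 ± 1.43 CPM against 8.59 ± 0.614 CPM. That call was lost without wild type 1, wild type 2 or SnoN cKO 2 (adjusted p of 0.0601, 0.104 and 0.37).

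Genes of the choroid plexus and of the meninges fell too, but rested on few libraries. All 14 choroid plexus and ependyma genes had negative log2 fold changes (median -0.30, adjusted p = 0.00272 by camera, adjusted p = 0.671 with an estimated correlation). Ttr, the transthyretin gene and the most abundant choroid plexus transcript, was at 17.3 CPM in SnoN cKO 2 and between 1641 and 3209 CPM in the other 5 libraries. Without SnoN cKO 2 the list turned to a median of 0.13 in the other direction (adjusted p = 0.0199), and without wild type 1 it did not pass (median -0.19, adjusted p = 0.0888). Without wild type 3, SnoN cKO 1 or SnoN cKO 3 its median was -0.51, -0.64 and -0.61. Meninges and fibroblast genes had 13 of 14 members negative, with a median of -0.14 (adjusted p = 0.00121, adjusted p = 0.671 with an estimated correlation). Collagen gene Col1a1 was at 162 ± 4.51 CPM against 195 ± 23.1 CPM. The meninges call was lost without wild type 1 or SnoN cKO 1 (adjusted p of 0.168 and 0.298), and without SnoN cKO 3 the median was -0.26.

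Markers of other cells of the cerebellum shifted by small amounts. Purkinje cell genes rose by a median of 0.06, with 14 of 16 positive (adjusted p = 0.0429 by camera, adjusted p = 0.671 with an estimated correlation). In that list the calcium-binding protein gene Calb1 was at 424 ± 24.6 CPM against 387 ± 20.2 CPM and Lhx5 at 56.7 ± 5.56 CPM against 48.7 ± 4.31 CPM. Microglia genes rose by a median of 0.06, with 13 of 15 positive (adjusted p = 0.0395, adjusted p = 0.671 with an estimated correlation). The adaptor gene Tyrobp was at 8.03 ± 0.338 CPM against 6.51 ± 0.176 CPM and the complement gene C1qb at 20.2 ± 2.01 CPM against 17.1 ± 0.505 CPM. The Purkinje call was lost without wild type 1, wild type 2 or SnoN cKO 2 (adjusted p of 0.24, 0.135 and 0.521), and the microglia call without wild type 2, wild type 3, SnoN cKO 2 or SnoN cKO 3 (adjusted p of 0.104, 0.227, 0.509 and 0.0838).

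Astrocyte and Bergmann glia genes did not pass as a list (9 of 16 positive, adjusted p = 0.568), yet 4 of them passed when adjusted over the list alone (adjusted p = 0.0469 from edgeR for each), and 0 over all genes. None of the 4 passed with any 1 library left out, and without SnoN cKO 3 only Gja1 did (adjusted p over the list alone 0.0068). Hopx, Aqp4, the water channel of astrocyte endfeet, and Fabp7, a fatty acid binding protein of radial and Bergmann glia, had log2 fold changes of 0.19, 0.15 and 0.15. Slc1a2, a glutamate transporter of mature astrocytes, was at 297 ± 12.95 CPM against 331 ± 12.2 CPM. GABAergic interneuron, endothelium and pericyte, and red blood cell genes did not pass as lists, with adjusted p of 0.144, 0.494 and 0.144. Of the GABAergic interneuron genes 8 of 12 were positive, and the transcription factor gene Tfap2a had a log2 fold change of 0.16 (SE 0.06) and the glycine transporter gene Slc6a5 of -0.24. Of the endothelium and pericyte genes 9 of 15 were positive, and the tight junction gene Cldn5 had a log2 fold change of 0.13 (SE 0.06) and the receptor gene Flt1, with the smallest p of the list, of -0.17. The globin gene Hbb-bt had a log2 fold change of -0.41 (SE 0.39). The red blood cell list had 6 measured members, all negative, and fell without wild type 1 or SnoN cKO 3 (adjusted p of 1.01e-07 and 0.000897). With an estimated correlation and all libraries its adjusted p was 0.713. In the oligodendrocyte, choroid plexus, meninges, Purkinje, microglia, GABAergic interneuron, endothelium and red blood cell lists 0 genes passed, adjusted over the list alone or over all genes tested.

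**Figure D3:**
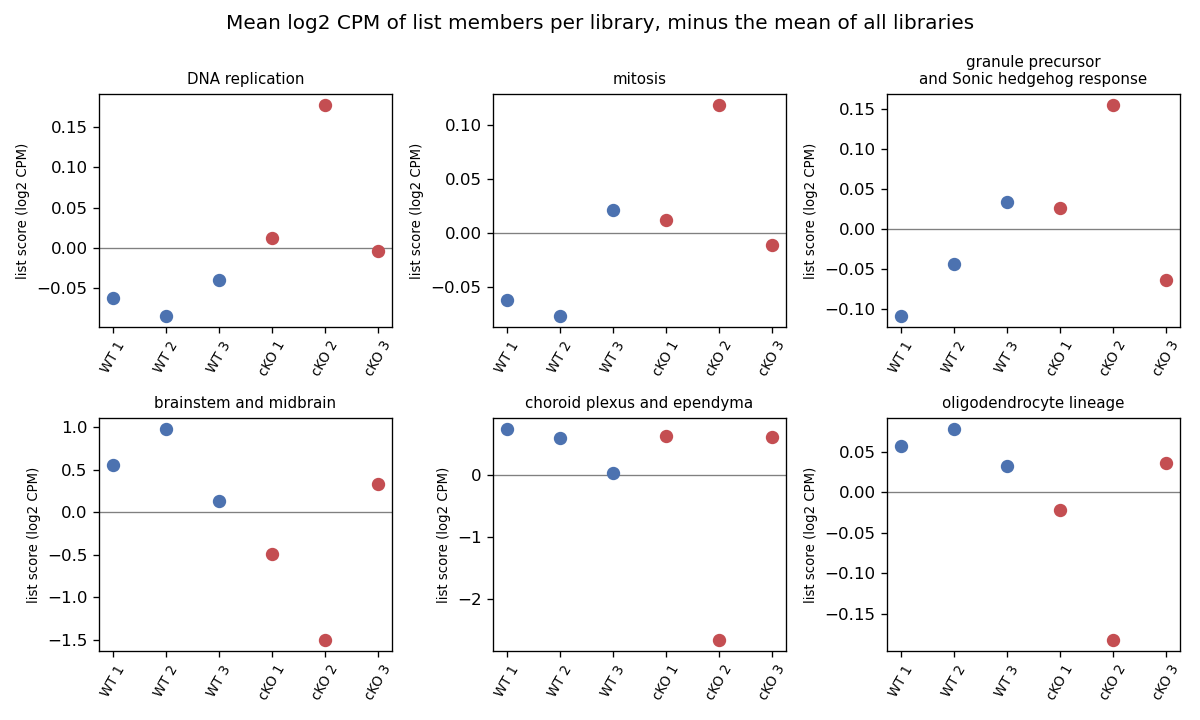
Score of 6 gene lists per library (vertical axes, mean log2 CPM of the members minus the mean of the 6 libraries; WT, wild type in blue; cKO, SnoN cKO in red; each panel has its own scale). SnoN cKO 2 has the highest DNA replication score, 0.18, and the lowest brainstem and choroid plexus scores, -1.51 and -2.68.

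The labelled sex of the animals was compared with sex-linked transcripts. Xist, the RNA of the inactive X chromosome, was at 2607 CPM in wild type 1, which is labelled female, and at 2536 CPM in SnoN cKO 2, which is labelled male. In the other 4 libraries Xist was between 2.52 and 3.28 CPM. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to between 267.9 and 297.5 CPM in wild type 2 and 3 and SnoN cKO 1 and 3, and to 0.0782 and 0.338 CPM in wild type 1 and SnoN cKO 2. The library labelled female in the SnoN cKO group and a library labelled male in that group therefore went against their labels, while the 3 wild type libraries and SnoN cKO 3 went with theirs. Skil was low in both, at 76.0 CPM in SnoN cKO 1 and 74.7 CPM in SnoN cKO 2.

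Only Ide passed the edgeR comparison of animals labelled female with animals labelled male, and 390 genes had an unadjusted p under 0.05. Ide, the insulin-degrading enzyme gene, was lower in the libraries labelled female by a log2 value of -0.52 (SE 0.05, adjusted p = 0.035 by edgeR's quasi-likelihood test). It was at 185.2, 252.0 and 253.5 CPM in wild type 1, 2 and 3 and at 124.4, 190.6 and 185.4 CPM in SnoN cKO 1, 2 and 3. Xist, at a log2 value of 7.15 (SE 4.89), did not pass, with 2 libraries against their labels. DESeq2 called Ide and Hba-a1. Without wild type 1, 2 or 3 in turn 0 genes passed, and without SnoN cKO 2 or 3 there were 6 and 3. Without SnoN cKO 1 only Nrgn passed (log2 value 2.79, adjusted p = 0.0168 by edgeR). No gene passed the test of an interaction between genotype and labelled sex (0 of 15457 by edgeR's quasi-likelihood test, 429 at an unadjusted p under 0.05, 35 and 71 past the adjusted threshold without SnoN cKO 2 and 3, and 4 by DESeq2, namely AC149090.1, Nov, Nrgn and Xist). Nrgn, the neurogranin gene, came nearest with an adjusted p of 0.376, at 34.9 CPM in wild type 1 and between 4.20 and 5.53 CPM in the other libraries. Ide, Btaf1, Fgfbp3, Nrgn and Ttr were named after their values were seen. Since 2 of 6 labels went against the sex-linked transcripts, neither fit compares animals of known sex.

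**Figure D4:**
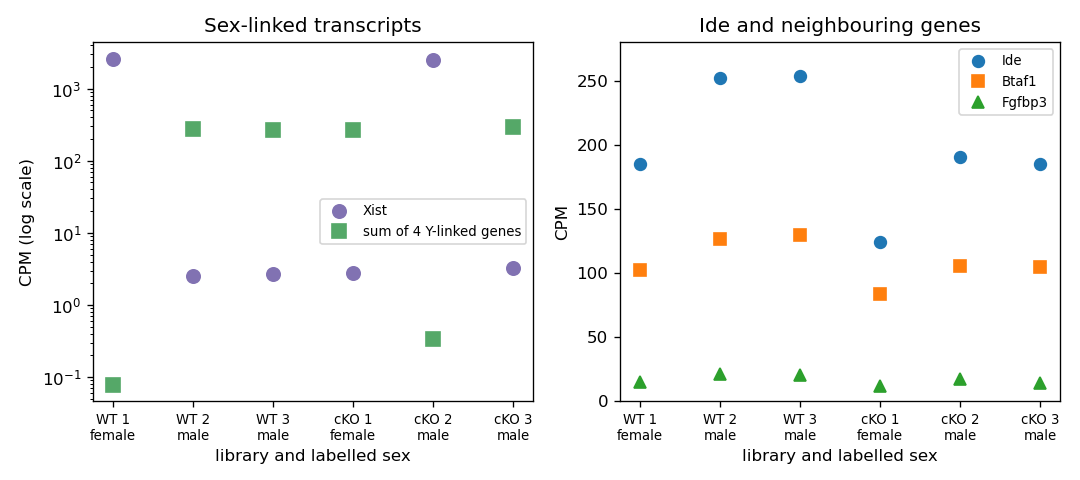
Left, Xist and the sum of 4 Y-linked genes per library in CPM on a log scale, with the labelled sex under each library; SnoN cKO 1 and 2 lie opposite to their labels. Right, CPM of Ide, Btaf1 and Fgfbp3 per library, with Ide between 124.4 and 253.5 CPM.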

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

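The removal of ribosomal-type genes, the removal of 2 pairs of libraries and the brainstem score as a covariate were chosen after seeing the data. Skil was lower in SnoN cKO in all 21 alternatives run for it, with log2 fold changes between -0.24 and -0.19 and unadjusted p between 0.000308 and 0.00989. For the other 99 named genes, 1980 of 2060 values kept their sign and their side of the threshold. In 64 values, from 27 genes, the sign turned without passing, and in 16 a gene passed. No gene had an adjusted p under 0.637 in the main fit, and most named genes were chosen for a small p. Few values could therefore change side, and these counts are weak evidence of stability. Where a value is given for an alternative without its reason, the cause was not tested.

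With edgeR's quasi-likelihood test 0 genes passed with DESeq2 size factors, limma-voom in its place, scaling by library total, the filter of 1 CPM, an adjusted p of 0.1, the 4 libraries labelled male, either removal of genes, wild type 2 and SnoN cKO 3 left out, or any 1 library left out. DESeq2 called 6 genes, 1 higher and 5 lower in SnoN cKO. Without a filter on low counts 39 passed, 8 higher and 31 lower. The likelihood ratio test called 5, with 2 higher and 3 lower. With the labelled sex as a covariate 1 passed, Ide, which was lower (1). With SnoN cKO 1 and 2 left out, which leaves 1 SnoN cKO library assumed to vary like the wild type, 7 passed, all 7 higher. With the brainstem score as a covariate 11 passed, all 11 higher. All of these were highest in SnoN cKO 3, where ribosomal-type genes held 5.11% of counts, and 2 of the 7 and 6 of the 11 were themselves ribosomal-type genes. With the replicate number as a block 0 genes passed, with 786 at an unadjusted p under 0.05, and 10 lists passed. Libraries with the same number did not deviate together (correlations of -0.04, -0.32 and -0.18), and none correlated best with its own number, so the numbers were not read as pairs. Under the block the Purkinje list did not pass (adjusted p = 0.0633) and the red blood cell list did (adjusted p = 0.00228).

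The number of lists past the threshold was 10, and between 6 and 11 with 1 library left out. It was 3 with SnoN cKO 1 and 2 left out, 1 with the brainstem score as a covariate, 0 for camera with an estimated correlation and 0 for fry. With 1 library left out, adjusted p ranged from 5.9e-16 to 0.000119 for DNA replication, 2.07e-10 to 0.0128 for mitosis, 8.28e-09 to 0.509 for granule precursor, 0.0751 to 0.898 for migrating and 0.116 to 0.618 for maturing granule genes. For the choroid plexus list they ranged from 2.11e-06 to 0.0888, and it turned direction without SnoN cKO 2 (0.0199). For camera with an estimated correlation adjusted p was 0.671 for the DNA replication, mitosis and granule precursor lists, and for fry 0.557, 0.557 and 0.674. In the 4 libraries labelled male the granule precursor (0.143), Purkinje (0.198) and oligodendrocyte (0.0564) lists did not pass, and the meninges list turned direction (0.719). The red blood cell list passed as lower there (4.1e-05), without a filter on low counts (0.00786), with the labelled sex as a covariate (0.0372) and with wild type 2 and SnoN cKO 3 left out (0.00574). With wild type 2 and SnoN cKO 3 left out the maturing granule list passed as lower (0.0478).

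With SnoN cKO 1 and 2 left out, adjusted p was 0.404 for mitosis, migrating granule and maturing granule genes. The granule precursor (0.449), choroid plexus (0.363) and meninges (0.404) lists turned direction there. With the brainstem score as a covariate, adjusted p was 0.673 for DNA replication, 0.0592 for migrating and 0.470 for maturing granule genes. The mitosis (0.727), granule precursor (0.152), Purkinje (0.654), oligodendrocyte (0.654), choroid plexus (6.97e-07) and brainstem (0.727) lists turned direction, the last because the covariate is its own score.

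Genes that differed by labelled sex numbered 1 with edgeR, 158 without a filter, 2 with DESeq2, and 0 to 6 with 1 library left out. Genes with an interaction of genotype and labelled sex numbered 0 with edgeR, 61 without a filter, 4 with DESeq2, and 0 to 71 with 1 library left out. Both fits without a filter called Gm42418. It was at 6921 CPM in wild type 2, 565 CPM in wild type 3 and 39052 CPM in SnoN cKO 3, all labelled male. The calls did not reflect that spread, so the 158 and 61 genes carry little weight. The interaction could not be fitted without wild type 1 or SnoN cKO 1, since no labelled female was left in that genotype. DESeq2 and the likelihood ratio test gave no list values. On simulated counts at this depth the edgeR test recovered 46% of genes changed 1.5-fold and 2% at 1.2-fold, so differences of the size seen in Skil were mostly below what a test over all genes could detect.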

Other observations

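Of the genes lower in SnoN cKO that DESeq2 or edgeR's likelihood ratio test called, 4 are given here with their levels, chosen after their values were seen. Cbln2, a secreted organizer of synapses, was at 7.39 ± 1.59 CPM against 14.6 ± 3.94 CPM in wild type, and Col11a2, a fibrillar collagen gene, at 18.3 ± 1.92 CPM against 28.3 ± 5.23 CPM. Hs3st2, a sulfotransferase of heparan sulfate, was at 3.56 ± 0.761 CPM against 6.57 ± 0.783 CPM, and Ank2, a membrane adaptor of axons, at 560 ± 28.3 CPM against 657 ± 16.3 CPM. In these 4 genes the libraries of the genotypes did not overlap, which 13.7% of all genes showed, where chance gives 10%. None passed edgeR's quasi-likelihood test (adjusted p = 0.637 for each).

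The tests on the DNA replication list and on splits of the libraries were written before their results were seen, and those on the sex-linked genes, on Ide and on the neighbours of Skil after.

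The DNA replication list was higher in SnoN cKO by a median log2 fold change of 0.14. Without SnoN cKO 2, the library with little Ttr, the median was 0.08 (0.0771) with 32 of 42 genes higher (adjusted p = 0.000119 by camera). This met the outcome set in advance for a difference not carried by that library, a passing list with a median of at least 0.0685. The median exceeded that bound by less than its bootstrap SE (0.01), a margin that was not part of the rule. The bootstrap resampled list members, which vary together (estimated correlation 0.486 with all libraries), so this SE does not measure the spread between animals. How much of the difference that library carries was therefore not decided. With the brainstem score as a covariate the median was 0.01 (0.00929) with 23 of 42 genes higher, and the call ended because the fold shrank, while the median SE of a gene went from 0.07 to 0.08. A smaller share of brainstem tissue in the SnoN cKO libraries may therefore account for part of the shift, although the score rests on 10 of 26 listed genes, all at 1 CPM or more in wild type (Slc5a7 highest, 8.86 CPM), and it also differs between genotypes, so the covariate takes up part of any genotype effect. An effect of the loss of SnoN stays open and was not tested apart from tissue share.

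Xist and Y-linked genes of SnoN cKO 1 and 2 went against their labels, and those of the other 4 libraries went with theirs. An exchange of the labels or libraries of SnoN cKO 1 and 2 with each other may explain it, since 2 libraries of that genotype were against their label, 1 in each direction. A mixture of RNA from both sexes is argued against by the minor sex signal of SnoN cKO 1 and 2, at most 0.122% of its level in the libraries that have it. An exchange with a wild type library is argued against by Skil, at 76.0 CPM in SnoN cKO 1 and 74.7 CPM in SnoN cKO 2. The wild type libraries were between 87.5 and 89.5 CPM. In wild type SD the distances from the wild type mean were -12.6 and -13.9. That SD rests on 3 libraries with close values, so these distances may overstate how firm the argument is. Errors in the recorded sex of both animals stay open, no biological explanation was tested, and the genotype comparison does not depend on which of the pair is which.

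Ide, Btaf1 and Fgfbp3 had stepped levels over the libraries, with Ide at 2.98, 4.05, 4.08, 2.0, 3.07 and 2.98 units of 62.2 CPM in wild type 1, 2, 3 and SnoN cKO 1, 2, 3, where the unit sets SnoN cKO 1 to 2. Their neighbour Cpeb3, also chosen after its values were seen, did not follow these steps. In the same order of libraries it was at 36.1, 39.5, 34.7, 31.6, 27.5 and 33.0 CPM. Loss of SnoN alone is argued against by the spread of Ide inside each genotype, where the lowest library was 0.733 of the mean of the others in wild type and 0.661 in SnoN cKO, and a library-wide difference by Tnks2 and Kif11, whose highest library was at most 1.13 times the lowest. As many whole copies of Btaf1 as of Ide, with levels in proportion, are argued against by Btaf1, which was at a mean of 2.48 (spread 0.09) of its own units in the 3 libraries where Ide was nearest to 3, while Fgfbp3 at 2.59 (spread 0.39, 151 counts in the lowest library) leaves that open. Copies of a segment holding Ide that differ in number between the mice may underlie its steps and stay open, because Ide lay within 0.0771 of whole units but was chosen for its steps, with a unit taken from its own lowest library. The segment around Ide and Fgfbp3 is known to vary in copy number among C57BL/6 mice, DNA was not analysed here, and a difference between the parents of the animals was not tested.

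Among the 20 tested genes nearest to Skil in the gene order of an annotation of a later build, 5 had an unadjusted p under 0.05, 3 of them lower in SnoN cKO (Cldn11, Slc7a14 and Zmat3) and 2 higher (Mynn and Actl6a), a number reached by 1.93% of 10000 windows. Ribosomal-type RNA genes held 1.09% of counts in wild type 2 and 5.11% in SnoN cKO 3, and between 0.233% and 0.291% in the other libraries.

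The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. By edgeR's quasi-likelihood test the real split gave 0 genes past the threshold and the highest other split gave 2 genes. DESeq2, which called 6 genes in the real split, was not run on the other splits. Because the real count was 0, 10 of 10 splits gave as many by construction. At an unadjusted p under 0.05 the real split gave 1187 genes and the highest other split 1742. The real split gave 10 lists past the threshold and the highest other split 12, with 5 splits giving as many. By camera, the unadjusted p of the DNA replication list was 1.14e-13 in the real split and 7.11e-10 at its lowest in another. The mitosis list went the other way, with an unadjusted p of 2.31e-08 in the real split and 1.29e-11 at its lowest in another. For Skil the unadjusted p by edgeR's quasi-likelihood test was 0.000379 in the real split and 0.219 at its lowest in another.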
